A study of Mus musculus with 3 samples.

How the data were processed

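Single-cell RNA sequencing of vascular tissue from wild-type mice was used, with 3 libraries, 1 each for vehicle, sunitinib and sunitinib plus Yoda1. Cells were digested from arteries, suspended in a MACS buffer and captured with the 10x Genomics Chromium 3' kit, per the labels' protocols. The protocols name no sort or gate beyond that buffer. The authors deposited, per library, a matrix of raw UMI counts per gene and cell barcode, not normalized. The matrices were made with Cell Ranger 6.0.0 (vehicle and sunitinib) and 7.1.0 (sunitinib plus Yoda1), per the file headers. Genome build mm10 and the tools Cell Ranger and Seurat are named, without versions, per the submitters' processing notes. Cell Ranger counts intronic reads by default from version 7 on and did not before. Whether that default was kept is not given in the sources used here, nor is the gene annotation. All 3 matrices list the same 32285 genes. They hold called cells alone, with lowest barcode totals of 501, 500 and 500 UMIs.

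Totals were 73901343, 66769480 and 28364203 UMIs. Cells with at least 500 UMIs, at least 300 detected genes and at most 15% mitochondrial UMIs were kept, which left 3947, 4148 and 3130 cells and left out 544, 358 and 1988 barcodes. Scrublet (as in scanpy 1.11.5, Python 3.11.15), run per library, marked 11 of 11225 cells (0.0980%). A caller that marks so few has not worked, so doublets were in effect not removed. An alternative added after the data were seen removed the 341 cells with the highest scores instead (0.8% per 1000 cells of the library). Counts were scaled to a common total and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 were used on the 3 libraries together without batch integration. Each cluster was given the class, among 25 sets of marker genes, whose markers had the highest mean log2 fold of the cluster's CPM over the median CPM of all clusters, with 10 CPM added to both. At least 3 markers had to be 2-fold higher and present in at least 25% of its cells. A cluster in which another class had more markers among the top 10 genes by fold stayed unnamed, as did one of low UMI count with none of its own markers there. Cluster 20 held 3 endothelial and 3 erythroid markers among these and kept its endothelial name. Class shares carry exact (Clopper-Pearson) binomial intervals.

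UMIs were summed per class and library for classes with at least 50 cells in each library, and given as CPM of the sum. The naming rule asked for 4 classes, but 2 qualified. Log2 ratios carry the exact conditional binomial interval of a ratio of 2 counts. A count of 0 was set to 3 counts, which makes the ratio a bound, and no ratio is given where the 2 counts sum to 3 or less. Counts of 1 and 2 were left as they were. In a ranking by ratio, a gene with 0 UMIs in 1 library can therefore stand nearer to 0 than a gene with 1 or 2. No p-value, standard error or count of changed genes was made, since cells are not replicates and each group has 1 library. Groups, filters, markers, 36 gene lists (34 of pathways, cell states and cell types and 2 of checks), the rule for named genes and most alternatives were fixed before the data were examined. A further 6 lists were added afterwards and are used in the closing section. Of these, 2 also stand beside the comparison of both compounds with sunitinib. The list of leukocyte transcripts stands beside that with vehicle too. A list's value is the median log2 ratio over members with at least 20 UMIs in the 2 libraries. Its interval comes from 1000 Poisson redraws of the counts, and its percentile from 10000 random lists of the same size matched on expression in 20 bins. A median is called here where it is at least 0.32 in size and its interval excludes 0, a rule set for description and not a test.

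Named genes are the 3 with the highest and the 3 with the lowest ratio per class for sunitinib against vehicle and for sunitinib plus Yoda1 against sunitinib. They needed a UMI in at least 10% of the cells of one library, at least 50 UMIs over both libraries, and a CPM of at least 1 in 10 of that in the class with most. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes were left out. Piezo1, the kinases inhibited by sunitinib and the 2 highest and 2 lowest members of each list described were named as well. Some genes that the rule names are not reported here. Coordinates are those of the GENCODE vM21 annotation on GRCm38, the assembly that mm10 names, counted from 1. Total intron length is the span of a gene less its exons, and 14438 of 14441 genes with at least 20 UMIs (99.98%) had one.

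The scripts were tested on simulated counts in which 200 genes had a known fold. In smooth muscle-like cells, 99.0% of genes simulated 2-fold apart came out at least 1.5-fold apart for sunitinib against vehicle (13945 genes) and 74.0% for sunitinib plus Yoda1 against sunitinib (13176 genes), and 3.02% and 23.8% of unchanged genes did so by chance. In endothelial-like cells the shares were 96.0% and 87.0%, and 9.37% and 8.35% of unchanged genes. Intervals of single genes covered the simulated value for 93.0% to 99.0% of genes. Coverage by the redraw intervals of medians was not worked out, and a drawn 0 was set to 3 counts there too. These intervals are approximate where counts are low. For sunitinib plus Yoda1 against sunitinib in smooth muscle-like cells, that of all genes with the shortest introns (0.004 to 0.048) missed its own median (-0.012). The simulated counts held counting error alone, as the intervals assume, so spread between cells or animals was not covered.

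Alternatives were mitochondrial limits of 5% and 25%, at least 1000 UMIs per cell, no doublet removal, resolutions of 0.5 and 2.0, 3000 variable genes with 50 components, cells thinned to at most 3738 UMIs (115, 411 and 782 cells already lay at or under that number), libraries clustered separately, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0, R 4.3.3), the mean over cells of each cell's CPM, 5% of UMIs taken off as free RNA, other minimums of UMIs, and the largest cluster of a class alone. Added after the data were seen were the removal of cells by doublet score, the endothelial-like cluster found in all 3 libraries, smooth muscle-like cells without clusters of low UMI count, and genes of short intron length alone. Other versions were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.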

Results

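Cells from digested arteries of wild-type mice were profiled by droplet-based single-cell RNA sequencing of transcript 3' ends, in which each captured molecule carries a unique molecular identifier (UMI). The mice had received vehicle, sunitinib, or sunitinib together with Yoda1, and all samples were labelled 3 weeks. Sunitinib is a small-molecule inhibitor of receptor tyrosine kinases, among them the VEGF and PDGF receptors, and is given against tumours. Yoda1 is a small-molecule agonist of PIEZO1, a cation channel opened by membrane stretch. The series title places the work in the study of heart damage by kinase inhibitors and of protection through PIEZO1. Each group was 1 library. No difference given here therefore has a replicate check, no test between groups was made, and every interval is a nominal 95% interval for counting error only. Intervals of medians are approximate where counts are low. The label of the sunitinib library names a TKI, and the series design lists sunitinib as the only compound given by itself. The label of the library with both compounds names Yoda1 alone. It was placed in the group given sunitinib plus Yoda1 because the series design lists no other group with Yoda1.

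The vehicle library held 4491 barcodes with 73901343 UMIs (median 15691 per barcode), and the sunitinib library held 4506 barcodes with 66769480 UMIs (median 15338). The sunitinib plus Yoda1 library held 5118 barcodes with 28364203 UMIs (median 4484). After filters on depth, detected genes, mitochondrial share and doublets, 3942, 4147 and 3125 cells remained. The file headers name Cell Ranger 6.0.0 for the vehicle and sunitinib libraries and 7.1.0 for the library with both compounds.

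The vehicle and sunitinib libraries consisted almost wholly of smooth muscle-like cells, and the sunitinib plus Yoda1 library consisted mainly of lymphocytes. Smooth muscle-like cells, defined by contractile genes such as Acta2 and Myh11, made up 95.1% of vehicle cells (94.4 to 95.7, exact binomial interval) and 94.4% of sunitinib cells (93.6 to 95.04). They made up 2.91% of cells in the sunitinib plus Yoda1 library (2.35 to 3.56; 91 of 3125 cells). Endothelial-like cells, defined by genes such as Pecam1 and Cdh5, made up 4.29% of vehicle cells (3.68 to 4.97), 5.35% of sunitinib cells (4.69 to 6.08) and 12.3% of cells with both compounds (11.2 to 13.5). In that last library B cell-like cells made up 41.0% (39.3 to 42.8), T cell-like cells 23.9% (22.4 to 25.5), fibroblast-like cells 8.10% (7.16 to 9.11) and macrophage-like cells 4.22% (3.55 to 4.99). No T cell-like cell was found in the vehicle or the sunitinib library, which at a limit of 3 cells allows a share of up to 0.0761% and 0.0723% (upper limits of the exact interval 0.0935% and 0.0889%). The median depth of kept cells was 16561 UMIs in vehicle, 15903 in sunitinib and 5452 with both compounds, before doublets were removed. The endothelial-like share with both compounds was 1.28% at a coarser clustering resolution of 0.5, and the macrophage-like share was 8.19% with 3000 variable genes and 50 components. When cells above 5% mitochondrial UMIs were left out, the smooth muscle-like share with both compounds was 0.153%. The endothelial-like shares were then 16.2%, 22.1% and 12.3% in vehicle, sunitinib and both compounds, so that the order of the libraries turned, and B cell-like cells (25.5%) no longer outnumbered T cell-like cells (26.7%).

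**Figure D1:**
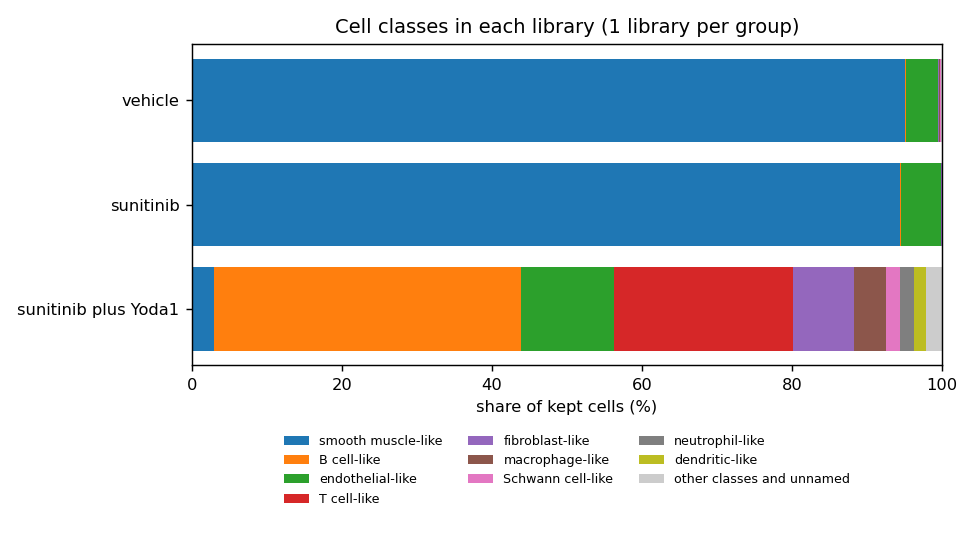
Horizontal stacked bars show the share of kept cells (%) in each named class for the 3 libraries, 1 library per group. Smooth muscle-like cells fill 95.1% of the vehicle bar and 94.4% of the sunitinib bar but 2.91% of the sunitinib plus Yoda1 bar, where B cell-like and T cell-like cells take 41.0% and 23.9%.

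Only smooth muscle-like and endothelial-like cells reached 50 cells in every library, and UMIs were summed within these classes. The comparison of sunitinib with vehicle asks what the kinase inhibitor alone did to cells of the vessel wall. In smooth muscle-like cells (3748 vehicle and 3913 sunitinib cells) heat shock, immediate early and cytokine genes were lower with sunitinib, though immediate early genes were not within the largest cluster. Of 34 gene lists, 8 had a median log2 ratio of -0.32 or lower with an interval that excluded 0, and 0 had a median as far above. The other 26 medians lay between -0.19 and 0.18. Of the 8 called medians, 1, that of heat shock genes, kept the size set for a call under every alternative run, and 7 did not.

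Heat shock genes, which encode chaperones of protein folding, had the lowest median (log2 ratio -0.69, interval -0.70 to -0.67), and 8 of the 13 members were at least 1.5-fold lower. Hspa1b, an inducible HSP70 chaperone that shares near-identical sequence with Hspa1a, stood at 410 CPM (UMIs scaled to a common total) in vehicle and 149 in sunitinib (log2 ratio -1.46, -1.50 to -1.43). Dnaja1, a co-chaperone of HSP70, had a ratio of -1.10 (-1.12 to -1.07). The members closest to 0 were Bag3 (-0.35) and Cryab (-0.29). Immediate early genes, which are induced within minutes by growth factors, stress or tissue dissociation, had a median of -0.45 (-0.46 to -0.44), with 8 of 20 members at least 1.5-fold lower. Myc had a ratio of -1.91 (-2.03 to -1.79) and Egr1 one of -0.84 (-0.85 to -0.83), while Cebpd (-0.13) and Btg2 (-0.11) lay closest to 0. Inflammatory cytokine and NF-kappaB genes had a median of -0.53 (-0.74 to -0.28; 4 of 9 members at least 1.5-fold lower), led by the neutrophil chemokines Cxcl2 (-3.56, -5.23 to -2.27) and Cxcl1 (-1.81, -2.04 to -1.60), with Nfkb1 at -0.10 and Nfkbiz at 0.03. Cxcl2 was also among the top 10 genes by fold of the macrophage-like cluster, which held 5 vehicle and 0 sunitinib cells. Whether RNA of such cells gave part of its ratio was not tested.

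Genes of dedifferentiated (modulated) smooth muscle had a median of -0.48 (-0.58 to -0.42), and 5 of 14 members were at least 1.5-fold lower. Spp1, which encodes osteopontin, stood at -2.84 (-4.22 to -1.70) and the proteoglycan gene Dcn at -1.74 (-2.07 to -1.43), whereas Lgals3 (0.24) and Col8a1 (0.43) were higher. Spp1 was also among the top 10 genes by fold of the macrophage-like cluster (5 vehicle and 0 sunitinib cells). Dcn was among those of the fibroblast-like cluster (9 and 5 cells). Whether RNA of such cells gave part of these 2 ratios was not tested. TGF-beta target genes had a median of -0.35 (-0.37 to -0.34), with 3 of 15 members at least 1.5-fold lower, among them Tgif1 (-0.92) and the cell cycle inhibitor Cdkn1a (-0.71). Acta2 (0.24) and Ltbp2 (0.26) were the highest members of that list. Leukocyte adhesion genes had a median of -0.48 (-0.67 to -0.10; 6 members), with Icam2 at -1.01 (-2.42 to 0.26), Cx3cl1 at -0.66, Vcam1 at 0.07 and Selplg at 0.41. Genes of angiogenic endothelium, measured here in smooth muscle-like cells, had a median of -0.46 (-0.57 to -0.33; 12 members), from Dll4 at -2.50 (-4.90 to -0.74) and Esm1 at -1.77 to Nrp2 at 0.02 and Pgf at 0.76. Contractile genes had a median of 0.18 (0.16 to 0.19), below the size set for a call, with 12 of 14 members above 0 and none 1.5-fold higher. Medians of random lists matched on expression were lower than this one in 99.97% of 10000 draws, which describes these libraries only and is not a test. The contractile median was 0.09 with TMM factors and 0.08 with median-of-ratios factors. The median over all 13945 genes measured was 0.09 by CPM, 0.007 with TMM factors and -0.007 with median-of-ratios factors.

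The clusters that held most smooth muscle-like cells were 3, 5 and 0 in vehicle and 4, 0 and 1 in sunitinib. Within cluster 0 alone (524 vehicle and 818 sunitinib cells) the heat shock median was -0.78, but the medians of immediate early genes (0.14), TGF-beta targets (0.07), leukocyte adhesion genes (0.33) and modulated smooth muscle genes (0.25) turned to the other side of 0. Those of NF-kappaB and cytokine genes (-0.20), angiogenic genes (-0.14) and the sunitinib target kinases (-0.10) lay under the size set for a call. By the mean over cells of each cell's CPM, the leukocyte adhesion median was -0.10, and with cells thinned to at most 3738 UMIs that of angiogenic genes was -0.26 and that of NF-kappaB and cytokine genes -0.30. The clusters were formed with the list genes included.

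By the fixed rule of size, the single genes that stood highest with sunitinib in smooth muscle-like cells were Grap, Slc25a33 and Arrdc2. Grap, an adaptor of receptor tyrosine kinase signalling, stood at 2.40 CPM in vehicle and 9.24 in sunitinib (log2 ratio 1.95, 1.70 to 2.20) and stood at 4.87 CPM in the sunitinib plus Yoda1 library. Slc25a33, a mitochondrial pyrimidine nucleotide carrier, had a ratio of 1.60 (1.51 to 1.69) and 14.6 CPM in that library, and Arrdc2 had a ratio of 1.55 (1.34 to 1.76) and 5.69 CPM there. The genes that stood lowest encode transcription factors. Fosl1, a subunit of AP-1, stood at 19.0 CPM in vehicle, 3.91 in sunitinib and 2.44 with both compounds (sunitinib against vehicle -2.28, -2.48 to -2.09). Myc stood at 43.2, 11.5 and 6.50 CPM, and Irf1, an activator of interferon-induced genes, at 61.1, 18.1 and 23.6 CPM (-1.75, -1.85 to -1.66). The smooth muscle-like sum with both compounds was 1231069 UMIs of 91 cells. Values of a few CPM there, as for Grap, Arrdc2, Fosl1 and Myc, rest on few UMIs, and no difference from sunitinib is read from them. Fosl1 (ENSMUSG00000024912) lies on chromosome 19 at 5447547 to 5455946 (plus strand, mm10) and overlaps Ccdc85b on the other strand. Hspa1b (ENSMUSG00000090877) lies on chromosome 17 at 34956436 to 34959238 (minus strand), Myc (ENSMUSG00000022346) on chromosome 15 at 61985391 to 61990374 (plus strand), and Grap (ENSMUSG00000004837) on chromosome 11 at 61653265 to 61672784 (plus strand). All values count UMIs over the whole gene, and whether strand was used in counting is not given in the sources used here.

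In endothelial-like cells (169 vehicle and 222 sunitinib cells) genes of antigen presentation, the interferon response and heat shock were lower with sunitinib. Of the 34 lists, 7 had a called median below 0 and 3 a called median above 0, and the other 24 lay between -0.26 and 0.24. The split was 12 below and 2 above with TMM or median-of-ratios factors, which shifted every ratio by -0.10 and -0.11. Antigen presentation genes had a median of -0.59 (-0.77 to -0.47), with 7 of 14 members at least 1.5-fold lower. Cd74, the invariant chain of MHC class II, stood at 1177 CPM in vehicle, 297 in sunitinib and 89.1 with both compounds (sunitinib against vehicle -1.99, -2.12 to -1.86). Ciita, the transactivator of MHC class II genes, stood at -2.13 (-3.58 to -0.89), while Tap1 (-0.18) and Nlrc5 (0.07) had intervals that included 0. Interferon response genes had a median of -0.48 (-0.61 to -0.33; 5 of 17 members at least 1.5-fold lower), with Zbp1 at -1.9999 (-3.79 to -0.50) and the GTPase gene Gbp2 at -1.26 (-1.50 to -1.01), and with Oasl2 (0.28) and Ifi27l2a (0.30) highest. Heat shock genes had a median of -0.63 (-0.71 to -0.55; 8 of 13 members at least 1.5-fold lower), from Hspa1b at -1.39 and Dnajb1 at -0.96 to Hsp90ab1 at -0.32 and Hspe1 at -0.01. NF-kappaB and cytokine genes had a median of -0.60 (-0.81 to -0.33; 5 of 9 members at least 1.5-fold lower), with Il1b at -4.17 (-6.50 to -2.54), Cxcl2 at -1.20, Relb at 0.05 and Cxcl12 at 0.10. Here too, RNA of macrophage-like cells (5 in vehicle and 0 in sunitinib) was not tested as a source of the Cxcl2 value. Leukocyte adhesion genes had a median of -0.38 (-0.49 to -0.30), with the fractalkine gene Cx3cl1 at -1.15 and Vcam1 at -0.50 against Selp at -0.29 and Sele at 1.27 (0.28 to 2.35). Modulated smooth muscle genes had a median of -0.34 (-0.52 to -0.15), with Sox9 at -2.56 and Ly6a at -0.98 against Fn1 at 0.15 and Thbs1 at 1.05. The modulated list lay under the size set for a call with free RNA taken off (-0.25), without the highest doublet scores (-0.29), by the mean over cells (-0.21) and thinned (-0.12). The adhesion list did so by the mean over cells (-0.21) and without those scores (-0.30), and the NF-kappaB list with no minimum of UMIs (-0.23). Immediate early genes had a median of -0.25 (-0.31 to -0.16), under the size set for a call.

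YAP and TEAD target genes, which respond to mechanical load and cell spreading, had a median of 0.36 (0.23 to 0.46) in endothelial-like cells. It lay under the size set for a call in 5 of 12 alternatives, among them 0.26 with TMM factors and 0.19 thinned. Ccn2 led them, with 603 CPM in vehicle and 1457 in sunitinib (1.27, 1.17 to 1.37), followed by Axl (0.65, -0.05 to 1.39), and Amotl1 (-0.25) and Fjx1 (-0.93) were lowest. A list of resident macrophage genes stood at 0.84 (0.53 to 0.93) but rested on 3 measured members, Gas6 (0.14), Selenop (0.84) and Cbr2 (0.96). Contractile smooth muscle genes in endothelial-like cells had a median of 0.46 (0.38 to 0.57), from Cnn1 at 0.03 and Myocd at 0.10 to Actg2 at 1.22 and Des at 1.66. That median turned to -0.66 when the cells with the highest doublet scores were removed, an alternative added after the data were seen. The highest single genes were Aldh1a1, a retinaldehyde dehydrogenase (2.14, 1.38 to 2.98), Slc25a44, a mitochondrial carrier of branched-chain amino acids (1.80, 0.78 to 2.96), and Klf15, a glucocorticoid-induced transcription factor (1.69, 1.04 to 2.39). Their levels in the sunitinib plus Yoda1 library were 1.86, 9.28 and 2.32 CPM, of 2155991 UMIs in the class. Those of Aldh1a1 and Klf15 rest on few UMIs, and no difference from sunitinib is read from them. The lowest were Il2rg, the common gamma chain of interleukin receptors (-2.34, -3.50 to -1.32), Cd74 and Phlda1 (-1.99, -2.81 to -1.23), and Il2rg and Phlda1 stood at 32.9 and 12.99 CPM with both compounds. Il2rg lies within a longer annotated gene on the same strand, Gm20489. Cd74 (ENSMUSG00000024610) lies on chromosome 18 at 60803848 to 60812652 (plus strand) and Aldh1a1 (ENSMUSG00000053279) on chromosome 19 at 20492715 to 20643465 (plus strand). Across 7071 genes measured in both classes, the sunitinib against vehicle ratios of the classes had a Pearson r of 0.398; genes are not independent replicates and both classes came from the same 2 libraries.

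**Figure D2:**
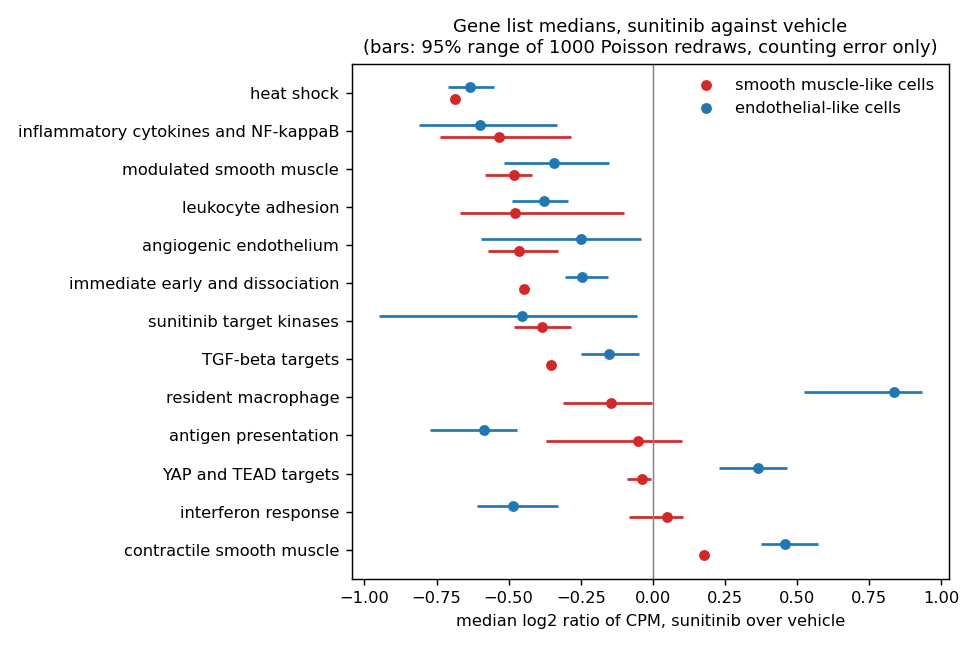
Points give the median log2 ratio of CPM, sunitinib over vehicle, for 13 gene lists in smooth muscle-like cells (red) and endothelial-like cells (blue), and bars give the 95% range of 1000 Poisson redraws of the counts. Heat shock genes lie at -0.69 and -0.63, and antigen presentation genes at -0.05 in smooth muscle-like and -0.59 in endothelial-like cells.

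Piezo1, the target of Yoda1, and the kinases that sunitinib inhibits were followed in every comparison. Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329, minus strand, overlapping Ctu2 on the other strand) was not detectably different between sunitinib and vehicle. Its log2 ratio was -0.22 (-0.45 to 0.02; 354 and 273 UMIs) in smooth muscle-like cells and -0.19 (-0.59 to 0.20; 107 and 110 UMIs) in endothelial-like cells. With both compounds it stood higher than with sunitinib, by 2.11 (1.43 to 2.73; 23 UMIs) and 1.48 (1.16 to 1.81; 301 UMIs). It holds 59697 bases of annotated intron, which puts it just under the upper bound (61976 bases) of the fourth of 5 equal groups of genes by intron length. The median ratios of all genes in that group were 0.45 and 0.38, and those of the group with the longest introns 1.07 and 1.06. The list of mechanosensitive channels, which includes Piezo1, had medians of 0.07 and -0.01 for sunitinib against vehicle. Pdgfrb, a PDGF receptor, was lower with sunitinib in smooth muscle-like cells (90.1 and 54.9 CPM; -0.72, -0.78 to -0.66), as were Kit (-0.57, -0.75 to -0.39) and Flt1 (-0.20, -0.33 to -0.07), while Pdgfra was higher (0.70, 0.42 to 0.98). In endothelial-like cells Flt1, which encodes VEGF receptor 1, stood at 69.7 CPM in vehicle and 31.9 in sunitinib (-1.13, -1.57 to -0.70), Pdgfrb at -0.45 (-0.95 to 0.04) and Flt4 at 0.03 (-0.79 to 0.86). The medians of the kinase list were -0.39 (-0.48 to -0.28; 4 members) and -0.45 (-0.95 to -0.06; 3 members). The smooth muscle-like median was -0.10 in the largest cluster and -0.28 at the 5% mitochondrial limit, both under the size set for a call, and the endothelial-like one was -1.001 by the mean over cells. Kdr, which encodes VEGF receptor 2, had 10 and 8 UMIs in endothelial-like cells, too few to show a difference (-0.56, -2.10 to 0.94). Csf1r, Flt3, Flt4, Kdr and Ret each had at most 6 UMIs in the smooth muscle-like cells of any library. Csf1r and Flt3 had 0 UMIs in endothelial-like cells of all 3 libraries, and Kit, Ret and Pdgfra had 2 or fewer in those of vehicle and sunitinib.

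The comparison of sunitinib plus Yoda1 with sunitinib asks what the PIEZO1 agonist added. Different clusters held the cells compared. Of the 91 smooth muscle-like cells with both compounds, 79 lay in cluster 21, which held no cell of the other libraries, and 345 of the 385 endothelial-like cells lay in cluster 20, with 1 vehicle cell and 0 sunitinib cells. A cluster found in 1 library may stand for that library rather than for a cell type. The labels give vascular tissue for all 3 libraries and do not say which vessel was taken, so whether the library with both compounds, mostly lymphocytes, came from the same vessel as the others is not known. In endothelial-like cells posterior Hox genes, which mark position along the body, had a median log2 ratio of -1.40 (-1.89 to -0.96; 6 members) and leukocyte transcripts one of 2.61 (1.54 to 3.53; 7 members), both lists added after the data were seen. Haemoglobin genes, whose alpha and beta copies share near-identical sequence, had a median log2 ratio of 12.14 (11.72 to 12.66) in smooth muscle-like cells and 13.60 (12.22 to 13.82) in endothelial-like cells.

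In smooth muscle-like cells immediate early, heat shock and TGF-beta target genes were lower with both compounds than with sunitinib, and 15 of the 34 lists had a called median above 0 and 6 one below. With TMM or median-of-ratios factors, which shifted every ratio by -0.43 and -0.40, the split was 5 above and 16 below. Of the 21 called medians, 9 kept the size set for a call under every alternative that gave a value. Immediate early genes had a median of -1.23 (-1.43 to -1.15), with 17 of 20 members at least 1.5-fold lower, from Ier3 at -2.56 and Ier5 at -2.50 to Fosl2 at -0.46 and Nr4a1 at -0.43. Heat shock genes had a median of -1.10 (-1.22 to -1.01; 10 of 13 members at least 1.5-fold lower), from Hspb1 at -2.45 and Hsph1 at -2.11 to Dnajb1 at -0.41 and Hspa1b at -0.24. TGF-beta targets had a median of -0.88 (-1.03 to -0.79; 11 of 15 members at least 1.5-fold lower), with Cdkn1a at -2.53 and Ccn2 at -1.92, and with Smad6 at 0.19 and Ski at 0.38. Antigen presentation genes had a median of 2.96 (1.90 to 3.42), with H2-Aa at 8.81 and Cd74 at 7.30 on 35 and 43 UMIs, and H2-D1 at -0.44 and B2m at -0.25. It was 0.25 after 5% of UMIs had been taken off as free RNA, 0.31 over members with at least 80 UMIs and 0.37 thinned. Interferon response genes had a median of 1.77 (1.42 to 2.03), with 13 of 14 members at least 1.5-fold higher, among them Ly6e (5.10) and Gbp3 (2.87), and with Ifit2 lowest at -0.48. Genes of smooth muscle calcium handling had a median of 0.93 (0.81 to 1.32), from Kcnmb1 at -0.17 and Atp2a2 at -0.01 to Pln at 4.56 and Trpc6 at 10.64 (8.05 to 15.99). That median was 0.51 with TMM factors, and too few members had short introns for a value over these alone, while the median over all genes with the longest introns was 1.07. Mechanosensitive channel genes had a median of 0.66 (0.34 to 0.84), with Pkd1 at -0.43, Tmem63a at 0.11, Piezo2 at 3.12 and Trpc6 highest. It was 0.23 with TMM factors. Genes of angiogenic endothelium had a median of 1.73 (1.16 to 1.998), which became -0.53 over genes of short total intron length alone. Flow-responsive genes had a median of -0.89 (-1.19 to -0.21), which became 0.20 when cells were thinned to at most 3738 UMIs.

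Among single genes in smooth muscle-like cells the highest ratios belonged to Ndufa4l2, one of the fixed pericyte markers (12.42, 9.91 to 17.74; 1 and 107 UMIs), Il31ra (12.04, 10.16 to 15.10; 2 and 164 UMIs) and Ebf2 (10.79, 8.88 to 13.86; 2 and 69 UMIs). Low ratios belonged to the stress-induced cytokine gene Gdf15 (-5.40, -8.44 to -3.54) and the centrin gene Cetn4 (-3.90, -9.21 to -1.42). Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456, minus strand) stood at 123 CPM in vehicle, 68.4 in sunitinib and 1.62 with both compounds. The median ratio over all 13176 genes measured was 0.34, and it was -0.08 with TMM factors and -0.06 with median-of-ratios factors.

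In endothelial-like cells the sunitinib target kinases and genes of angiogenic endothelium and basement membrane were higher with both compounds than with sunitinib, and contractile, elastic fibre and immediate early genes were lower. This sets mostly cluster 20 (Cd36, Gpihbp1 and Ly6c1 among its top 10 genes by fold) against cluster 8 (Cytl1, Vwf and Bmp4). A different kind of endothelial cell therefore cannot be told apart from a response to the compounds. Kdr and Flt1 are also among the markers behind the endothelial name. Of the 34 lists, 10 had a called median above 0 and 17 one below, and 12 of these 27 kept the size set for a call under every alternative that gave a value. For basement membrane, mechanosensitive channel, kinase and vascular tone genes the limit to short introns gave none. The kinase list had a median of 5.72 (3.93 to 5.91), with Kdr at 7.77 (6.78 to 8.98; 8 and 1710 UMIs), Kit at 5.88 (3.35 to 11.21), Flt1 at 5.72 (5.38 to 6.08; 70 and 3625 UMIs), Flt4 at 2.05 (1.46 to 2.68) and Pdgfrb at -0.95 (-1.59 to -0.34). Genes of angiogenic endothelium had a median of 3.09 (2.68 to 3.63; 12 of 14 members at least 1.5-fold higher), with Nrp2 and Kdr highest and Vegfa (-1.67) and Notch1 (0.06) lowest. Basement membrane genes had a median of 1.09 (0.90 to 1.44), with Lama4 at 3.40 and Nid2 at 3.11 against Col18a1 at -1.70 and Lamb2 at -0.82. The median over all genes with the longest introns was 1.06 in these cells. Contractile smooth muscle genes had a median of -3.84 (-4.16 to -3.62), from Cnn1 at -8.81 and Acta2 at -5.76 to Des at -0.63 and Smtn at -0.53. Without the highest doublet scores this median was -0.91 and Cnn1 stood at -5.16, and at the 5% mitochondrial limit the median was -2.10. These genes mark smooth muscle-like cells, which made up 94.4% of sunitinib cells and 2.91% of cells with both compounds. RNA of those cells therefore cannot be told apart from a change in endothelial-like cells. Interstitial matrix genes had a median of -2.50 that turned to 0.26 without the highest doublet scores. Matrix proteases had one of -0.59 that turned to 0.18 in the largest cluster, 0.19 with no minimum of UMIs and 0.40 over genes of short introns. Elastic fibre genes had a median of -2.16 (-2.62 to -2.08), with Mfap5 at -4.77, Mfap4 at or below -5.36 (0 UMIs with both compounds, set to 3 counts), Ltbp2 at -1.37 and Fbn1 at 0.71. Immediate early genes had a median of -1.44 (-1.66 to -1.36; 14 of 19 members at least 1.5-fold lower), with Fos at -3.32, Fosb at -2.73, Fosl2 at 0.05 and Ier5 at 0.49. Antigen presentation genes had a median of -1.05 (-1.11 to -0.98), with H2-DMa at -3.16 and H2-Ab1 at -1.86 against Tap2 at 0.55 and Nlrc5 at 1.33. Interferon response genes had a median of 0.85 (0.58 to 1.05), from Gbp3 at -0.77 and Gbp2 at -0.59 to Usp18 at 3.42 and Rsad2 at 6.21, beside the leukocyte transcripts at 2.61.

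Only cluster 8 of the endothelial-like cells was found in all 3 libraries (168, 222 and 40 cells). Within it the median of the kinase list was 1.39, that of angiogenic genes 0.23, basement membrane genes 0.33, elastic fibre genes -0.79, interferon response genes -0.31 and leukocyte adhesion genes 0.15, the last against -2.11 (-2.35 to -1.74) over the whole class. Immediate early genes (-1.39), antigen presentation genes (-0.9999) and contractile genes (-3.29) stayed on the same side there. The ratio of Piezo1 in that cluster was 1.32 and that of Kdr 1.97. Over all genes with the longest introns the median in that cluster was 0.78. The single genes with the highest ratios in the whole class were the fatty acid transporter gene Cd36 (12.67, 10.20 to 17.98; 1 and 6420 UMIs), which is also among the genes that define cluster 20, Dach1 (10.17, 7.69 to 15.47) and Cmss1 (10.05, 9.52 to 10.64), which overlaps Filip1l on the other strand. The lowest was the smooth muscle marker gene Cnn1 (-8.81, -14.11 to -6.32). Next came the calcitonin receptor co-receptor gene Ramp1 (-7.89, -13.20 to -5.40, and -4.16 without the highest doublet scores) and the keratin gene Krt18 (-7.64, -10.69 to -5.78). Cd36 (ENSMUSG00000002944) lies on chromosome 5 at 17781690 to 17888801 (minus strand). Dach1 and Cmss1 hold 375596 and 302868 bases of annotated intron.

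Ratios against sunitinib were higher the longer the introns of a gene. Between the longest and the shortest of 5 equal groups of genes the median log2 ratio of sunitinib plus Yoda1 against sunitinib differed by 1.08 (1.03 to 1.10) in smooth muscle-like cells and by 1.49 (1.46 to 1.53) in endothelial-like cells. The same gap between sunitinib and vehicle was -0.06 (-0.07 to -0.05) and 0.03 (0.01 to 0.07). Among genes of the 2 groups with the shortest introns, the median of immediate early genes with both compounds against sunitinib was -1.31 in smooth muscle-like and -1.65 in endothelial-like cells. The heat shock median in endothelial-like cells, -0.36 over all genes, was -0.11 without the highest doublet scores and -0.23 with free RNA taken off.

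**Figure D3:**
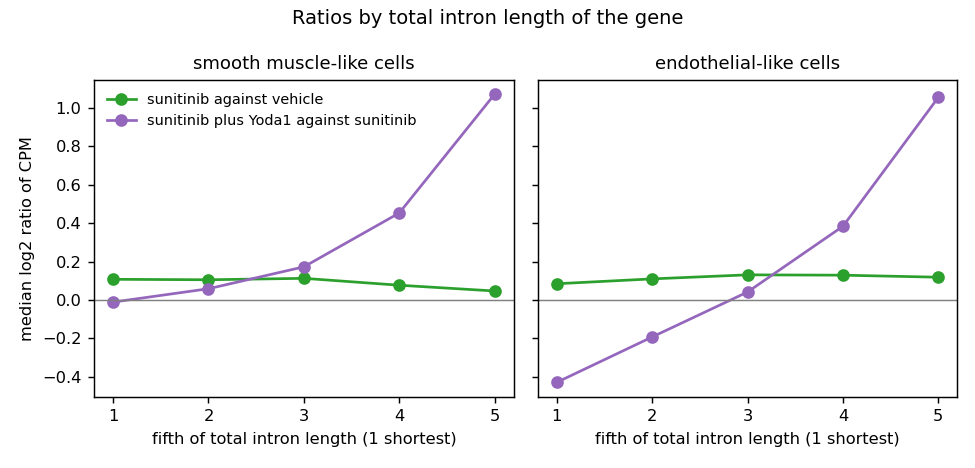
Median log2 ratio of CPM (vertical axis) over genes in 5 equal groups of total intron length, from shortest (1) to longest (5), in smooth muscle-like cells (left) and endothelial-like cells (right). The sunitinib plus Yoda1 against sunitinib line climbs by 1.08 and 1.49 from group 1 to group 5, while the sunitinib against vehicle line changes by -0.06 and 0.03.

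The comparison of sunitinib plus Yoda1 with vehicle asks whether values moved by sunitinib lay nearer to vehicle once Yoda1 was added. It shares its libraries with both other comparisons, and the cluster, depth and software differences named above hold for it too. Heat shock genes lay further below vehicle with both compounds than with sunitinib alone, at -1.76 (-1.92 to -1.64) in smooth muscle-like and -0.92 (-1.02 to -0.87) in endothelial-like cells. Immediate early genes did so too, at -1.93 (-2.07 to -1.83) and -1.59 (-1.71 to -1.49), as did antigen presentation genes in endothelial-like cells, at -1.51 (-1.56 to -1.26). The heat shock median against sunitinib in endothelial-like cells (-0.36) lay under the size set for a call in 6 of 13 alternatives. It was -0.09 at the 5% mitochondrial limit. The median of that comparison was -0.43 over all genes with the shortest introns, -0.19 over the next group and 0.15 over all genes measured. Heat shock genes were not matched on intron length to these groups. Whether the further fall there is particular to them is therefore undecided. Interferon response genes in endothelial-like cells, lower with sunitinib, lay above vehicle with both compounds over the whole class (0.54, 0.13 to 0.63; 0.29 with TMM factors, under the size set for a call). Beside them leukocyte transcripts, a list added after the data were seen, stood at 2.86 (2.15 to 3.62; 6 members). In cluster 8, found in all 3 libraries, interferon response genes were lower both in sunitinib against vehicle (-0.49) and with both compounds against sunitinib (-0.31). YAP and TEAD targets, higher with sunitinib, lay below vehicle over the whole class (-0.39, -0.65 to -0.13, and -0.63 with TMM factors). Their rise with sunitinib was under the size set for a call in 5 of 12 alternatives. NF-kappaB and cytokine genes stood at 0.56 (0.34 to 1.0006) in smooth muscle-like cells, or 0.050 with TMM factors. In endothelial-like cells they stood at -0.29 (-0.71 to -0.06), under the size set for a call, or -0.53 with TMM factors, over it. Piezo1 lay above vehicle by 1.90 and 1.28, where the median of all genes in its intron length group was 0.52 and 0.495 and that of the group with the longest introns 1.13 and 1.19. In all, 14 lists had a called median above vehicle and 7 one below in smooth muscle-like cells, and 9 and 17 in endothelial-like cells. With TMM factors, which shifted every ratio by -0.51 and -0.24, these splits were 6 and 15, and 5 and 19.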

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

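All tests below were chosen after the pattern they address had been seen, and those of handling, intronic reads, leukocytes, free RNA and single cells also after the value they measure. Barcodes that the cell filters left out of the sunitinib plus Yoda1 library stood out because 75.4% of their UMIs came from haemoglobin genes, against 21.8% in vehicle and 6.51% in sunitinib. Among kept cells of that library the share was 1.81%.

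The lists that follow stood out because their medians for sunitinib plus Yoda1 against sunitinib lay on opposite sides of 0 in smooth muscle-like and endothelial-like cells, a difference that was not tested. Vascular tone mediators had medians of 0.64 and -0.73, leukocyte adhesion genes 1.04 and -2.11, matrix proteases and their inhibitors 0.62 and -0.59, and antigen presentation genes 2.96 and -1.05. Vascular tone and antigen presentation kept opposite signs under every alternative that gave a value, and the other lists did not (too few vascular tone genes had short introns to give one there). In endothelial-like cells leukocyte adhesion turned to 0.15 in the shared cluster and matrix proteases to 0.18, 0.19 and 0.40 under 3 alternatives. In smooth muscle-like cells matrix proteases turned to -0.031 thinned, and with no change of sign antigen presentation stood at 0.25 with free RNA taken off and vascular tone at 0.21 with TMM factors.

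Heat shock and immediate early genes were lower in the sunitinib library. A different mix of vessel segments predicts smaller medians among smooth muscle-like cells with a UMI of a posterior Hox gene. In these (1966 vehicle and 2213 sunitinib cells) the medians were -0.67 (-0.69 to -0.65) and -0.46 (-0.47 to -0.44), close to -0.69 and -0.45 over the whole class. Such cells pool every segment that carries such a gene, so the mix among them is not known and a different mix stays open. Within the largest smooth muscle-like cluster the medians were -0.78 and 0.14. For immediate early genes a different mix of cell states, in clusters formed with these genes included, therefore stays open too. Handling that reached the whole library, such as the time or warmth of digestion, predicts lower values in endothelial-like cells too, and these were -0.63 and -0.25. An effect of the drug on both classes predicts the same and stays open, untested, since each group had 1 library.

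Genes with long introns were higher in the sunitinib plus Yoda1 library. Intronic reads counted in that library alone may be the source. The gap between the longest and the shortest introns was 1.08 in smooth muscle-like and 1.49 in endothelial-like cells against sunitinib, and -0.061 and 0.034 between sunitinib and vehicle. Other endothelial subtypes in that library were argued against as the whole source, because the gap was 1.30 (1.24 to 1.35) within the endothelial-like cluster found in all 3 libraries. The counting setting is not given in the sources used here, and an effect of the compounds on unspliced RNA stays open, untested.

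MHC class II genes were lower in sunitinib endothelial-like cells, with a median of -1.45 (-1.63 to -1.30) and 7 of 7 members lower. Without cells that carried a leukocyte UMI the median was -1.50, but this left 165 of 169 vehicle and 219 of 222 sunitinib cells. So small a removal could hardly move the median, and it cannot decide about leukocytes or doublets without such a UMI. The interleukin receptor gene Il2rg stood at -2.34 in the same class. Macrophage-like cells numbered 5 in vehicle and 0 in sunitinib, while B cell-like cells numbered 3 and 7. Free RNA was argued against by a Cd74 level in smooth muscle-like vehicle cells of 0.0699% of that in endothelial-like ones (0.822 and 1177 CPM). A few cells with very high levels were argued against by the share of cells with a Cd74 UMI at equal depth, 61.9% in vehicle (53.2 to 70.2; 134 cells) and 27.3% in sunitinib (20.4 to 35.0; 154 cells). That comparison left out 35 and 68 shallower cells, the unthinned shares were 69.8% and 31.5% at median depths of 8139 and 6789 UMIs, and in smooth muscle-like cells, which should lack the gene, the shares were 0.190% and 0.0839% at 16732 and 16105 UMIs. An effect of sunitinib and a difference between animals or libraries both stay open, untested, and more animals per group would be needed to tell them apart.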

How the results depend on the processing

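No paired analysis was possible because each group had 1 library. The removal of cells by doublet score, the limit to short introns, the shared endothelial-like cluster and the omission of clusters of low UMI count were chosen after the data were seen. In this part A is sunitinib against vehicle and B is sunitinib plus Yoda1 against sunitinib, values are median log2 ratios or shares of cells, and the value reported elsewhere stands in brackets. Called medians that kept at least 0.32 in size under every alternative that gave a value numbered 1 of 8 in A and 9 of 21 in B in smooth muscle-like cells, and 5 of 10 and 12 of 27 in endothelial-like cells. Called and followed lists that turned to the other side of 0 under no alternative run numbered 8 of 12 in A and 16 of 21 in B in smooth muscle-like cells, and 13 of 14 and 19 of 27 in endothelial-like cells. Over named genes, 383 values stayed within their counting interval and 37 moved out of it. Within their interval 3 values of 2 genes crossed 0, Pdgfra in B in smooth muscle-like cells (0.46) to -0.078 with free RNA taken off and Flt4 in A in endothelial-like cells (0.03) to -0.072 and -0.083 with TMM and median-of-ratios. For lists not printed one by one, 600 values stayed and 186 moved. The largest smooth muscle-like cluster and the 5% mitochondrial limit gave no value for B in smooth muscle-like cells, since under 10 cells with both compounds were left. Too few members had short introns to give a value in B for endothelial junction, mechanosensitive channel, kinase and vascular tone genes in both classes, for calcium handling genes in smooth muscle-like cells and for basement membrane genes in endothelial-like cells. In endothelial-like cells at least 80 UMIs gave none for the kinases in A or cell cycle genes in B, and thinning none for the kinases in A. Except where an alternative by its construction uses fewer cells or genes, the cause was not tested. In smooth muscle-like cells B rests on 1231069 UMIs of 91 cells with both compounds.

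Shares in vehicle, smooth muscle-like (95.1%), were 94.1% with 3000 variable genes and 50 components, 94.3% with at least 1000 UMIs, 94.2% without the highest doublet scores, 93.6% with libraries clustered separately and 81.7% at the 5% mitochondrial limit. Those in sunitinib (94.4%) were 92.7% with 3000 genes, 92.9% without the highest doublet scores and 76.4% at the 5% limit. With both compounds the smooth muscle-like share (2.91%) was 0.153% at the 5% limit. The endothelial-like share was 5.28% in vehicle (4.29%) with separate clustering and 16.2% at the 5% limit, 22.1% in sunitinib (5.35%) at the 5% limit, and with both compounds (12.3%) 13.8% at the 25% limit, 1.28% at resolution 0.5 and 10.5% at 2.0. The B cell-like share (41.0%) was 38.4% with 3000 genes, 38.8% without the highest doublet scores, 35.1% with separate clustering, 25.5% at the 5% limit, 32.3% without doublet removal, 32.3% at resolution 0.5 and 38.0% at 2.0. The T cell-like share (23.9%) was 22.4% with 3000 genes, 22.3% at the 25% limit and 26.7% at the 5% limit. The fibroblast-like share (8.10%) was 5.63% with separate clustering and 10.7% at the 5% limit. The macrophage-like share (4.22%) was 8.19% with 3000 genes, 6.88% without the highest doublet scores, 7.104% with separate clustering, 6.04% at the 5% limit and 6.98% at resolution 2.0.

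For A in smooth muscle-like cells, heat shock genes (-0.69) stood at -0.77 with TMM, -0.78 with median-of-ratios, -0.70 thinned, -0.78 in the largest cluster, -0.73 by the mean of cells and -0.67 at the 5% limit. Immediate early genes (-0.45) stood at -0.53, -0.54 and -0.42 with TMM, median-of-ratios and thinning, -0.39 by the mean of cells, -0.38 at the 5% limit and 0.14 in the largest cluster. Contractile genes (0.18) stood at 0.095, 0.081 and 0.19 with TMM, median-of-ratios and thinning and, at the 5% limit, 0.24. In the largest cluster TGF-beta targets (-0.35) turned to 0.071, leukocyte adhesion (-0.48) to 0.33 and modulated smooth muscle (-0.48) to 0.25. For A in endothelial-like cells, heat shock genes (-0.63) stood at -0.73 with TMM, -0.75 with median-of-ratios, -0.76 without the highest doublet scores and -0.42 at the 5% limit, and contractile genes (0.46) at -0.66 without those scores.

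For B in smooth muscle-like cells, immediate early genes (-1.23) stood at -1.66 with TMM, -1.64 with median-of-ratios, -0.97 thinned and -1.11 by the mean of cells. Lipid-associated macrophage genes (0.39) turned to -0.036 and -0.014 with TMM and median-of-ratios, cell cycle genes (0.75) to -0.046 with at least 80 UMIs, flow-responsive genes (-0.89) to 0.20 and matrix proteases (0.62) to -0.031 thinned, and angiogenic genes (1.73) to -0.53 with short introns. For B in endothelial-like cells, immediate early genes (-1.44) stood at -1.36 by the mean of cells. Resident macrophage genes (0.59) turned to -1.17 with at least 80 UMIs, -1.15 with free RNA taken off, -1.37 in the largest cluster, -1.10 at the 5% limit and -0.56 with no minimum. Matrix proteases (-0.59) turned to 0.40 with short introns, 0.18 in the largest cluster and 0.19 with no minimum, and interstitial matrix (-2.50) to 0.26 without the highest doublet scores. In the largest cluster cell cycle genes (0.59) turned to -0.065, NF-kappaB genes (0.45) to -0.28, interferon response genes (0.85) to -0.31, leukocyte adhesion (-2.11) to 0.15 and mesenchymal transition (-0.62) to 0.14.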

Other observations

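The gene lists in this paragraph and the next, and their tests, were chosen after the values had been seen. Genes induced by glucocorticoids had a median log2 ratio of sunitinib against vehicle of 0.55 (0.33 to 0.65; 11 members) in endothelial-like cells and 0.27 (0.24 to 0.29; 12 members) in smooth muscle-like cells. In endothelial-like cells Klf15 (1.69) and Pdk4 (1.59) were highest and Errfi1 (-0.40) and Dusp1 (-0.15) lowest. Fkbp5, a chaperone of the glucocorticoid receptor, had 2077 UMIs in vehicle and 5221 in sunitinib smooth muscle-like cells (1.49, 1.41 to 1.56). A hypothesis is that glucocorticoid signalling was higher in the sunitinib mice. It predicts a median above 0.32 in both classes, which was met in endothelial-like cells alone. The smooth muscle-like median was 0.51 in the largest cluster, 0.18 and 0.17 with TMM and median-of-ratios factors, 0.18 thinned, 0.17 over members with at least 80 UMIs and 0.090 at the 5% mitochondrial limit, so the tables do not decide.

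Clock genes also differed between these libraries. In smooth muscle-like cells genes that peak with Dbp had a median of 0.44 (0.33 to 0.57; 9 members), with Dbp at 1.33, Per3 at 1.22, Per2 at 0.08 and Nr1d1 at -0.37. Genes that peak with Arntl had a median of -0.77 (-1.01 to -0.58; 5 members), with Arntl at -1.36, Nfil3 at -1.23, Npas2 at -0.50 and Clock at -0.30. In endothelial-like cells the medians were 0.58 (0.35 to 0.88), with Bhlhe41 at 1.14 and Dbp at 1.05, and -0.12 (-0.69 to 0.31; 3 members). Collection of the tissue at different times of day could give such values, and it predicts opposite signs in both classes. The interval of the second list in endothelial-like cells included 0, so this stays undecided, and an effect of the drug on the clock was not tested.

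Other values are given without explanation. For sunitinib plus Yoda1 against sunitinib in endothelial-like cells, MHC class II genes had a median of -1.85. The posterior Hox medians for sunitinib against vehicle were 0.18 in smooth muscle-like and -0.03 in endothelial-like cells. MHC class II genes in smooth muscle-like cells had a median of -0.54 (-1.09 to -0.17) for sunitinib against vehicle. Genes of oxidative phosphorylation had medians of 0.16 in smooth muscle-like cells for sunitinib against vehicle, for the nuclear and for the mitochondrial genome. Haemoglobin genes stood at -2.46 (-3.05 to -2.06) there. Y-linked genes, a check on the sex of the mice, were measured in both classes, with medians of 0.32 and 0.17 for sunitinib against vehicle and 0.30 and 0.51 for both compounds against sunitinib.

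The ribosomal protein gene Rpl35 and the ribosomal sequence Rpl10-ps3, named after a pseudogene, were chosen after their values were seen. Rpl35 stood at 258, 82.2 and 533 CPM in smooth muscle-like cells of vehicle, sunitinib and both compounds and at 405, 134 and 495 CPM in endothelial-like cells (sunitinib against vehicle -1.65 and -1.60). Rpl10-ps3 stood at 35.5, 68.3 and 11.4 CPM in smooth muscle-like cells (sunitinib against vehicle 0.94, and 0.97 in endothelial-like cells). Ribosomal protein genes have near-identical copies elsewhere in the genome, so both values are uncertain.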
